A study of Rattus norvegicus with 18 samples.

How the data were processed

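RNA of the extensor digitorum longus of 18 adult F2 female rats was hybridized to 18 Affymetrix whole-transcript arrays, 200 ng per array, per the labels' protocols. The labels cross the diet of the grandfather (chow or high-fat) with the diet of the female for 12 weeks (chow or high-fat), in groups of 5, 5, 4 and 4 animals. The deposited table holds an intensity on a linear scale for each of 20917 probe sets on each array; per the submitters' processing notes it was made with Affymetrix Expression Console and PLIER, whose versions and settings are not given. The median deposited intensity of an array ran from 55.02 to 73.97, a range of 0.341 log2. For arrays there is no depth to give, and their number limits the precision. Of the probe sets, 19157 had a gene entry in the probe table supplied with the series (18197 with 1 symbol and 960 with several) and 1760 had none, for 16856 distinct symbols. Entrez identifiers of 18052 probe sets were matched to the RefSeq gene table of assembly GRCr8, which changed 0 symbols.

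Values were taken as log2(intensity + 16). Because the array medians differed by more than the 0.1 log2 set for this before the data were examined, quantile normalization (limma 3.58.1, R 4.3.3) was used, and the table as deposited became the alternative. Probe sets with exactly 1 symbol were kept, 1 per gene by the highest mean, with a mean above the 25th percentile (5.28 log2), which left 12642 genes. A group-means model of the 4 groups was fitted to all 18 arrays with lmFit and eBayes, with two-sided moderated tests and Benjamini-Hochberg adjustment over the 12642 genes within each comparison, at 0.05. The family held 7 comparisons: the own diet in each lineage, the grandpaternal diet at each own diet, the interaction, and the 2 averages. Sizes are log2 differences of group means with their standard errors and 95% confidence intervals. Of 31 gene lists, 30 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 30 lists within a comparison; of the mitochondrially encoded transcripts 0 were measured, so that list was not tested. Where a list is called, the adjusted p with an estimated correlation stands beside it. Of the lists, 8 are markers of other cell types or tissues that a whole muscle can hold, and the immediate early list stands for handling at dissection. The score of an animal for a list is the mean of its members after each gene was centred over all arrays. Agreement between 2 comparisons without shared animals was measured with Pearson's r over genes, against 100 redrawn groupings.

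Genes are named by a rule set before the data were examined, as were the groups, comparisons, lists and most of the other settings. In each comparison these are the 10 largest rises and the 10 largest falls among genes past the threshold or, where fewer than 10 genes passed, those and the genes of smallest p up to 10, with values only. In each list past its test they are the 3 or 4 members of smallest p in the direction of the list. Of a fixed panel, Pdk4, Ucp3, Angptl4, Cpt1b, Myh7, Slc2a4, Fbxo32, Adipoq and Scd are followed throughout, and its other members are not analysed here. A gene named in 1 comparison may be given in others; Plin1, Cidec, Retn, Cfd, Pck1, Pgs1 and Crls1 in the closing part were chosen after values were seen.

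Other settings fixed beforehand were the table as deposited, offsets of 1 and 64, no filter and a filter at the 50th percentile, all probe sets, trended and robust eBayes, array weights, a fit of the 2 groups compared alone, the well column of the array as a block, neighbouring animal numbers (3 or fewer apart in 1 lineage) as a random block, each array left out, and for lists an estimated correlation and fry. Chosen after seeing the data were centring on array medians, the deposited array median as a covariate, exact permutation of animals on list scores, and leaving out the 2 arrays of lowest median. The sample titles carry no shared replicate numbers, so no replicate block was fitted, and replicates are numbered in the order of the records. In the titles 3 wells occur more than once, each time for animals of different lineages, and the labels do not explain the wells. If they stand for more than 1 plate, the well column pools plates, and plate could go with the diet of the grandfather. Arrays of 1 group were checked for copies: over 32 pairs the smallest SD of the log2 difference was 0.189, and at most 0.0908% of values were identical. The fit was tested on simulated data with 12642 genes and known changes: at a log2 change of 0.5 it recovered 85.1% and 80.6% of changed genes for the own diet in the chow and high-fat lineages and 74.6% and 88.1% for the grandpaternal diet at own chow and high-fat diet; at a log2 change of 1 it recovered 98.5%, 100%, 98.5% and 98.5%. In each of these comparisons 67, 67 and 66 genes were changed by 0.5, 1 and 2 log2. Genes and animals were drawn independently, with no shift between arrays and no quantile step. So many planted changes ease the adjusted threshold, so the recovered shares do not give the power of the real comparisons. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).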

Results

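Gene expression was measured in the extensor digitorum longus, a fast hindlimb muscle, of 18 adult Sprague-Dawley females of the second filial generation (F2). Their founding grandfathers (F0) had been fed chow or a high-fat diet, and each F2 female then spent 12 weeks on chow or on a diet in which fat supplied 42/45% of the energy. The groups are named by the diet of the grandfather and then that of the female. The chow/chow and chow/high-fat groups held 5 animals each, and the high-fat/chow and high-fat/high-fat groups held 4 each. Every array carried RNA of a separate animal, and the number of arrays limits the precision. Animals are the replicates for the own diet. The diet of the grandfather was given to the F0 males, and the labels do not give how many founded each lineage. Comparisons of that diet also count each animal as independent, so relatives within a lineage could make the p-values of these comparisons too small. The deposited median intensity of the 20917 probe sets was 66.71, 68.59, 66.98, 70.52 and 66.29 on the chow/chow arrays and 62.66, 65.60, 66.45, 56.98 and 55.02 on the chow/high-fat arrays. It was 62.28, 60.21, 70.13 and 70.66 on the high-fat/chow arrays and 68.37, 73.78, 67.52 and 73.97 on the high-fat/high-fat arrays. Comparisons were made on log2 values of 12642 genes after quantile normalization, in a family of 7 comparisons, and the deposited table gives no genomic positions.

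The opening comparison asked what 12 weeks of high-fat feeding did to the muscle of the females themselves, averaged over both grandpaternal lineages. Decr1 (probe set 10875631), a mitochondrial reductase that unsaturated fatty acids need for their oxidation, rose 1.5-fold (log2 change 0.59, SE 0.094, 95% confidence interval 0.39 to 0.79, limma adjusted p = 0.0328). Its log2 level went from 7.89 ± 0.21 to 8.48 ± 0.24 in the chow lineage (SD, n = 5 and 5) and from 7.62 ± 0.086 to 8.22 ± 0.28 in the high-fat lineage (SD, n = 4 and 4). Nudt7 (10808159), a peroxisomal hydrolase of coenzyme A and its esters, rose 1.55-fold (log2 change 0.63, SE 0.10, 95% confidence interval 0.42 to 0.84, adjusted p = 0.0328). Both genes lay above the mean of their chow-fed counterparts in 9 of 9 high-fat-fed animals, and these were the 2 genes of 12642 that passed, against 851 at an unadjusted p under 0.05. Around them the genes of fatty acid oxidation rose as a list: 23 of 25 measured members were higher, by a mean of 0.24 log2 (camera adjusted p = 3.26e-26, adjusted p = 0.0553 with an estimated correlation). In this list 17 members passed when adjusted over the list alone and 1, Decr1, over all genes. Other members of smallest p were Mlycd (0.49, SE 0.10), the decarboxylase of malonyl-CoA, Cpt1b (0.20, SE 0.040), which passes long-chain fatty acids to mitochondria in muscle, and Crat (0.19, SE 0.039), the carnitine acetyltransferase, each at adjusted p = 0.0985 over all genes.

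Genes known to respond to fatty acids in muscle also rose as a list, with 17 of 17 measured members higher by a mean of 0.35 log2 (camera adjusted p = 2.13e-22, adjusted p = 0.0184 with an estimated correlation), 12 of them past the threshold adjusted over the list alone and 1 over all genes. The 2 lists share 7 measured genes, among them Decr1, Mlycd and Cpt1b, so they are not separate evidence. The score of each animal is the mean of the centred log2 values of a list. For oxidation it lay above the mean of the chow-fed counterparts in 9 of 9 high-fat-fed animals (two-sided exact permutation p = 0.000907, 0.0136 after adjustment over 30 lists). For the responsive genes it did so in 8 of 9 (exact permutation p = 0.000340, adjusted 0.0102). Aqp7, a glycerol channel, differed by 1.31 (SE 0.24, 2.48-fold, adjusted p = 0.0747). Plin5, a protein that coats lipid droplets, differed by 0.82 (SE 0.16, 1.76-fold, adjusted p = 0.0985). Neither passed. Both lay above the mean of their chow-fed counterparts in 9 of 9 high-fat-fed animals. As for Decr1 and Nudt7, that count largely follows from picking genes of small p in these same animals. It is not separate evidence. Pxmp4, a peroxisomal membrane protein, was higher by 0.31 (adjusted p = 0.0709), Tshz3 by 0.27 (0.0747), and Hsdl2, Rhobtb1 and Inpp4b by 0.31, 0.47 and 0.41 (each 0.0985). None of these passed. A further probe set of Inpp4b differed by -0.0055 log2 in this comparison. Of the fixed panel of metabolic genes, Pdk4, which restrains pyruvate oxidation, differed by 0.29 (SE 0.10, adjusted p = 0.618), Angptl4 by 0.62 (SE 0.29) and Ucp3 by 0.30 (SE 0.17). Fbxo32 differed by 0.14 (SE 0.073), the glucose transporter Slc2a4 by -0.19 (SE 0.068) and Scd by -0.30 (SE 0.19). Myh7 differed by 0.21 (SE 0.30) and Adipoq by 0.030 (SE 0.19). None of the panel passed.

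**Figure D1:**
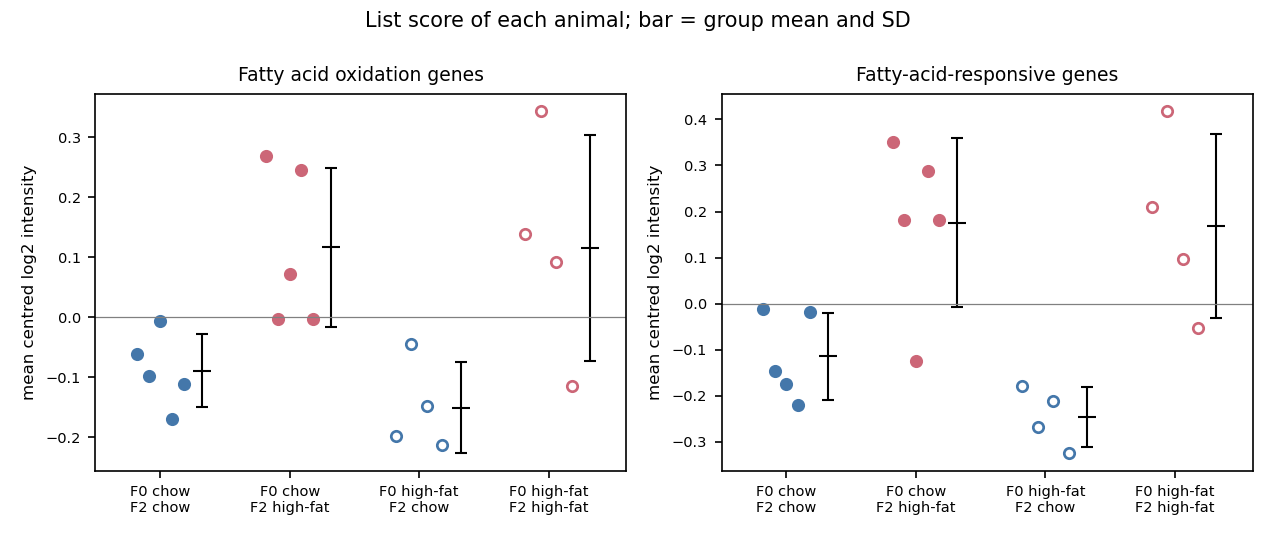
Score of each animal for the fatty acid oxidation list (left) and the fatty-acid-responsive list (right), in mean centred log2 intensity, by diet of the grandfather (F0) and of the female (F2); bars give group mean and SD. The oxidation score was -0.089 ± 0.061 in chow/chow, 0.12 ± 0.13 in chow/high-fat, -0.15 ± 0.076 in high-fat/chow and 0.12 ± 0.19 in high-fat/high-fat animals.

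Markers of other cell types went in both directions with the own diet. The fat-cell marker list rose by a mean of 0.17 but a median of 0.043 log2 (camera adjusted p = 0.00295, adjusted p = 0.241 with an estimated correlation), with 12 of 14 members higher and 3 passing adjusted over the list alone, 0 over all genes. Its members of smallest p were Aqp7, Cidea (0.43, SE 0.15), Lipe (0.40, SE 0.11) and Plin4 (0.11, SE 0.062), several of which muscle fibres also express (another probe set of Lipe gave 0.12), while Adipoq, made by fat cells, differed by 0.030. Fibroblast and matrix genes fell as a list, with 32 of 33 lower by a mean of -0.16 (camera adjusted p = 3.70e-12, adjusted p = 0.241 with an estimated correlation), as in Dcn (-0.20, SE 0.060), Timp2 (-0.23), Col6a3 (-0.22) and Col1a1 (-0.40, SE 0.15). Leukocyte markers fell by a mean of 0.15 log2, 24 of 26 being lower (camera adjusted p = 6.85e-09, adjusted p = 0.241 with an estimated correlation), for example Cybb (-0.28), Mrc1 (-0.23), Cd68 (-0.20) and Itgam (-0.16). In both lists 0 members passed, adjusted over the list alone or over all genes. Tendon markers averaged -0.23 with 11 of 12 lower (camera adjusted p = 0.000121, adjusted p = 0.373 with an estimated correlation). Among them were Chad (-0.57), Thbs4 (-0.40), Col14a1 (-0.32) and Cilp2 (-0.27). Interferon-stimulated genes averaged -0.092 with 17 of 21 lower (camera adjusted p = 0.00118, adjusted p = 0.373 with an estimated correlation). Ifi27 (-0.46, adjusted p = 0.246), Irf7 (-0.23), Tap1 (-0.21) and Ifit2 (-0.16) were among these. In each of the 2 lists 1 member passed adjusted over the list alone and 0 over all genes. Immediate early genes, which handling and activity induce, averaged 0.12 with 23 of 27 higher (camera adjusted p = 0.00913, adjusted p = 0.563 with an estimated correlation). Examples are Ier5 (0.13), Egr3 (0.12), Nr4a3 (0.37) and Zfp36 (0.22). Proteasome subunits averaged -0.041 with 27 of 32 lower (camera adjusted p = 0.00640, adjusted p = 0.563 with an estimated correlation), as in Psmb7 (-0.14), Psmb4 (-0.13), Psmc6 (-0.085) and Psmd12 (-0.080). In these last 2 lists 0 members passed adjusted over the list alone or over all genes. Without chow/chow replicate 3 (0.10, adjusted p = 0.0699), chow/high-fat replicate 1 (0.061, adjusted p = 0.154), high-fat/chow replicate 1 (0.097, adjusted p = 0.0975) or high-fat/high-fat replicate 1 (0.10, adjusted p = 0.0900) the immediate early list missed the threshold. The proteasome list did so without chow/high-fat replicate 1 (-0.026, adjusted p = 0.154) or high-fat/chow replicate 4 (-0.032, adjusted p = 0.0758), and as deposited (-0.043, adjusted p = 0.0503). The immediate early mean was 0.19 without the 2 arrays of lowest median.

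The other 21 lists did not pass in this comparison. Among energy pathways, nuclear genes of the respiratory chain differed by a mean of -0.0060 log2 over 70 genes and the tricarboxylic acid cycle by -0.0027 (median 0.0060). Glycolysis differed by -0.032, glucose uptake and insulin signalling by -0.016, lipid synthesis by 0.037 and sterol synthesis by 0.021. Slow-fibre genes differed by 0.036 and fast-fibre genes by -0.035 (camera adjusted p = 0.0582), regeneration genes by 0.0021 and atrophy genes by 0.017. Markers of red blood cells differed by 0.15, of nerve by 0.023, of endothelium by -0.030 and of vessel walls by 0.026. Chaperones differed by -0.0014, clock genes by 0.0099, antioxidant genes by 0.0011 (median -0.0078), cell cycle genes by -0.000021, imprinted genes by 0.0052, let-7 targets by 0.0081 and chromatin modifiers by 0.0033. Within the 3 well columns in which arrays were placed, the oxidation list differed by 0.28, 0.055 and 0.45 log2 in columns 5, 7 and 9. In column 9 only the high-fat lineage could be compared, with 2 high-fat-fed animals against 1 chow-fed animal, for this and the following lists. The responsive list differed by 0.39, 0.19 and 0.64 in the same columns. The fibroblast list differed by -0.16, 0.034 and -0.24, the leukocyte list by -0.25, 0.082 and -0.10 and the tendon list by -0.095, -0.099 and -0.34. So the fibroblast and leukocyte lists turned sign in column 7. There 4 high-fat-fed animals were set against 2 chow-fed animals, 1 of each lineage, for all these lists. That turn therefore rests on single chow-fed animals. The number of genes called depended on single animals and was 0 without chow/chow replicates 2, 4 or 5, chow/high-fat replicates 1, 2, 4 or 5, high-fat/chow replicates 2, 3 or 4 or high-fat/high-fat replicates 1, 2 or 3. It was 1 without chow/chow replicate 1 or high-fat/chow replicate 1. Without chow/chow replicate 3 it was 4. It was 14 without high-fat/high-fat replicate 4. Decr1 and Nudt7 both missed the threshold with an offset of 1 (adjusted p = 0.0554), with the deposited array median as a covariate (0.0554) and without the 2 arrays of lowest median (0.0958), and the count was 0 in each. It was 4 as deposited, 5 with arrays centred on their medians, 5 with trended and robust eBayes, 6 with array weights and 6 with an offset of 64. The well column as a block gave 15 and neighbouring animal numbers as a random block 14.

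**Figure D2:**
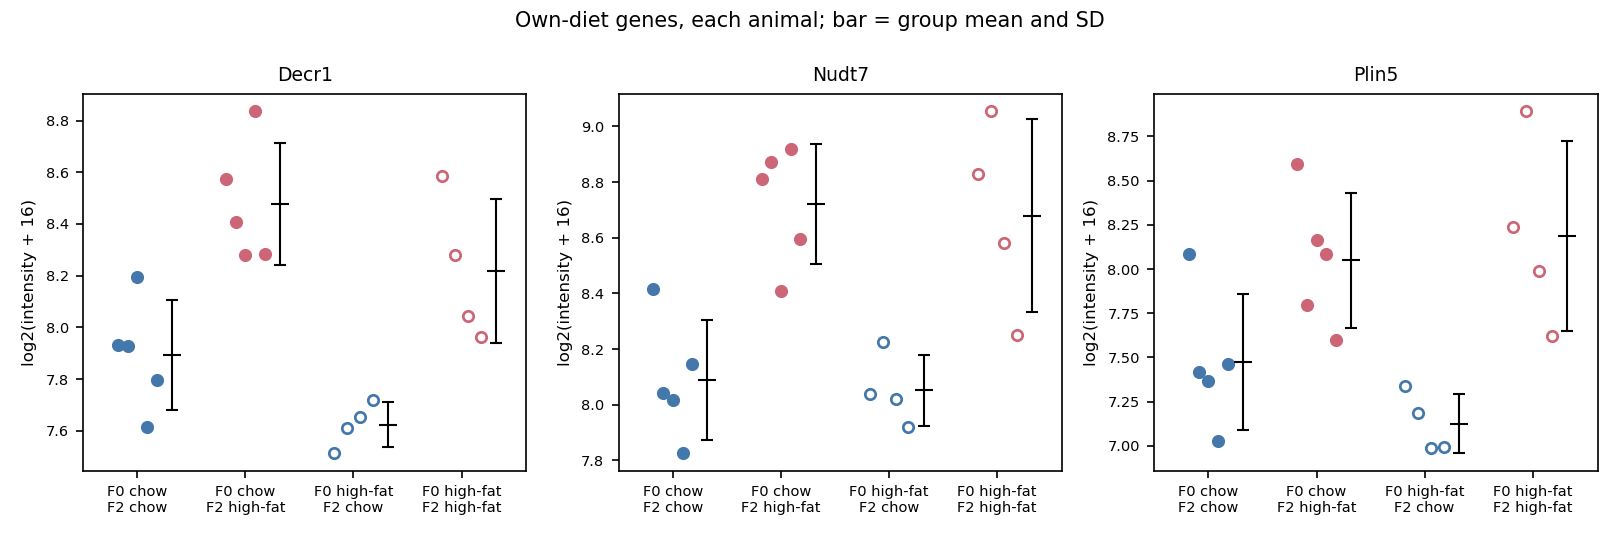
Level of Decr1, Nudt7 and Plin5 in each animal, in log2(intensity + 16), by diet of the grandfather (F0) and of the female (F2); bars give group mean and SD. Plin5 went from 7.47 ± 0.38 to 8.05 ± 0.38 in the chow lineage and from 7.13 ± 0.17 to 8.18 ± 0.54 in the high-fat lineage, and it did not pass the test over all genes.

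In granddaughters of chow-fed males, the own diet gave its smallest adjusted p for genes including Sntb1, a protein of the dystrophin complex (-0.74, SE 0.15), Smo, the hedgehog signal transducer (-0.44), and Tmem106a (-0.40), each with adjusted p = 0.225, so none can be called changed. Inpp4b (0.53) and Zfp157 (-0.34) had the same adjusted p, though another probe set of Inpp4b gave 0.072. They were followed by Nudt7 (0.63, SE 0.13) and Decr1 (0.58, SE 0.12) at 0.288, then LOC680428 (0.46), Acsl4 (0.43) and Cers4 (-0.32). The oxidation list rose, 22 of 25 members being higher by a mean of 0.21 (camera adjusted p = 2.12e-14, adjusted p = 0.236 with an estimated correlation), with Decr1, Mlycd (0.54), Ech1 (0.43) and Cpt1b (0.19) leading. The responsive list rose by a mean of 0.29, 14 of 17 higher (camera adjusted p = 1.53e-11, adjusted p = 0.223 with an estimated correlation). The fat-cell marker list rose by 0.19, 10 of 14 higher (camera adjusted p = 0.00104, adjusted p = 0.236 with an estimated correlation). It was led by Aqp7 (1.22, SE 0.32), Lipe (0.37), Plin1 (0.17) and Cidea (0.40), with 0.11 for another probe set of Lipe. Adjusted over the list alone, 7, 6 and 1 members of these 3 lists passed, and 0 over all genes. Two-sided exact permutation of the 5 and 5 animals gave p = 0.00794 for the oxidation score, the smallest these groups can give, and p = 0.0238 for the responsive score, each 0.238 after adjustment over 30 lists.

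Also in the chow lineage, 5 lists fell. Slow-fibre genes were lower in 16 of 16 by a mean of -0.28 (camera adjusted p = 0.00562, adjusted p = 0.875 with an estimated correlation). Examples are Csrp3 (-0.40), Ankrd2 (-0.44), Pln (-0.23) and Myoz2 (-0.36). Fibroblast and matrix genes averaged -0.13, 30 of 33 lower (camera adjusted p = 7.89e-06, adjusted p = 0.540 with an estimated correlation), with Dcn (-0.25), Tgfb1 (-0.18), Nid1 (-0.24) and Bgn (-0.27) leading. Leukocyte markers averaged -0.13, 21 of 26 lower (camera adjusted p = 7.34e-05, adjusted p = 0.540 with an estimated correlation), with Cd4 (-0.37), Coro1a (-0.19), Tyrobp (-0.24) and Cd163 (-0.31). Another probe set of Cd4 gave -0.022. Tendon markers averaged -0.32, 11 of 12 lower (camera adjusted p = 6.76e-06, adjusted p = 0.318 with an estimated correlation), as in Thbs4 (-0.67), Scx (-0.34), Col14a1 (-0.27) and Chad (-0.57). Interferon-stimulated genes averaged -0.11, 16 of 21 lower (camera adjusted p = 0.00111, adjusted p = 0.445 with an estimated correlation), as in Ifit2 (-0.32), Ifi27 (-0.34), Irf7 (-0.26) and Ifit3 (-0.19). In these 5 lists 0 members passed, adjusted over the list alone or over all genes. The panel genes Pdk4 (0.19), Ucp3 (0.30), Angptl4 (0.49), Myh7 (-0.35), Slc2a4 (-0.10), Fbxo32 (0.062), Adipoq (0.20) and Scd (-0.39) did not pass. limma called 0 genes, with 607 at an unadjusted p under 0.05 and 632.1 expected by chance. As deposited, the median of all genes shifted by -0.13 log2 and 1 gene passed, lower. The slow-fibre call was lost without chow/chow replicate 1 (-0.17, adjusted p = 0.221), chow/chow replicate 3 (-0.20, adjusted p = 0.104), chow/high-fat replicate 2 (-0.12, adjusted p = 0.367) or chow/high-fat replicate 4 (-0.23, adjusted p = 0.0572). It was also lost as deposited (-0.42, adjusted p = 0.485), with the well column as a block (-0.10, adjusted p = 0.625) and without the 2 arrays of lowest median (-0.18, adjusted p = 0.189). In neighbouring pairs of animals, a comparison made after the values were seen, the high-fat-fed female had the lower slow-fibre score in 5 of 5 pairs. The slow-fibre mean was -0.44 without chow/high-fat replicate 1. The fibroblast call was lost with the well column as a block (-0.064, adjusted p = 0.0511); its mean was -0.081 without chow/chow replicate 5 and -0.074 without chow/high-fat replicate 2. The leukocyte mean was -0.19 without chow/chow replicate 3, -0.082 without chow/chow replicate 5 and -0.079 without chow/high-fat replicate 1. Without the 2 arrays of lowest median these 2 means were -0.22 and -0.20, and the tendon mean was -0.20 with the well column as a block. As deposited, with the shift of all genes in them, the means were 0.071 for oxidation, 0.15 for responsive, 0.088 for fat-cell, -0.28 for fibroblast and -0.25 for leukocyte genes, all 5 still called. The interferon call was lost without chow/chow replicate 4 (-0.068, adjusted p = 0.0833) or chow/high-fat replicate 1 (-0.077, adjusted p = 0.0779), and as deposited (-0.21, adjusted p = 0.151).

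In granddaughters of high-fat-fed males, Plin5 was 2.08-fold higher with the own high-fat diet (log2 change 1.06, SE 0.24, n = 4 and 4) and the peroxisomal enzyme Cat was higher by 0.44 (SE 0.092), both with adjusted p = 0.245 and so not called. The same adjusted p belonged to Dennd6b (0.37), Znfx1 (0.29), Tshz3 (0.35), Dpp3 (0.50), Rhobtb1 (0.63), Hspbp1 (0.33), Tlr3 (0.42) and Acot1 (0.53), which were higher, and to the kinase Pak1 (-0.58) and the cold-induced Rbm3 (-0.52), which were lower. The responsive list rose by a mean of 0.41, 16 of 17 higher (camera adjusted p = 1.54e-13, adjusted p = 0.131 with an estimated correlation), with Decr1 (0.59) and Acot2 (0.57) next to Plin5 and Acot1. The oxidation list rose by 0.27, 23 of 25 higher (camera adjusted p = 4.21e-15, adjusted p = 0.295 with an estimated correlation), with Crat (0.23), Hadhb (0.28) and Etfa (0.31). Adjusted over the list alone, 11 and 14 members passed, and 0 over all genes. Two-sided exact permutation of the 4 and 4 animals gave p = 0.0286, the smallest these groups can give, and p = 0.0571, each 0.429 after adjustment over 30 lists. Fibroblast and matrix genes fell by a mean of 0.19, 32 of 33 lower (camera adjusted p = 3.66e-07, adjusted p = 0.525 with an estimated correlation), as in Col6a2 (-0.32), Timp2 (-0.29), Col6a3 (-0.31) and Lama2 (-0.21). Leukocyte markers fell by 0.17, 24 of 26 lower (camera adjusted p = 6.44e-05, adjusted p = 0.525 with an estimated correlation), as in Cd68 (-0.31), Cybb (-0.39), Mrc1 (-0.30) and Itgam (-0.18). Immediate early genes rose by a mean of 0.22, 20 of 27 higher (camera adjusted p = 0.00957, adjusted p = 0.525 with an estimated correlation), as in Fos (1.03, SE 0.56), Egr1 (0.85), Nr4a3 (0.69) and Dusp1 (0.41). In these 3 lists 0 members passed, adjusted over the list alone or over all genes.

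In the same lineage slow-fibre genes averaged 0.35, 14 of 16 higher (camera adjusted p = 0.0270, adjusted p = 0.780 with an estimated correlation), led by Tnni1 (0.78, SE 0.44), Myh7 (0.77, SE 0.44), Myoz2 (0.59) and Atp2a2 (0.57). Fast-fibre genes averaged -0.050, 12 of 14 lower (camera adjusted p = 0.0499, adjusted p = 0.525 with an estimated correlation), as in Tpm1 (-0.16), Mybpc1 (-0.11), Pvalb (-0.10) and Tnnt3 (-0.066), but 0.0091 as deposited. That call held in only 3 of 18 runs that left out 1 animal, being lost without chow/chow replicates 1, 2, 3, 4 or 5, chow/high-fat replicates 2, 3, 4 or 5, high-fat/chow replicates 1, 3 or 4 or high-fat/high-fat replicates 1, 2 or 4 (means of -0.054 to -0.038, adjusted p from 0.0522 to 0.204). It was lost, too, without the 2 arrays of lowest median (-0.050, adjusted p = 0.0657), while with arrays centred on their medians the mean was -0.079. Proteasome subunits averaged -0.083, 27 of 32 lower (camera adjusted p = 0.000841, adjusted p = 0.525 with an estimated correlation), as in Psmb7 (-0.29), Psma2 (-0.30), Psma7 (-0.24) and Psmd13 (-0.17), but 0.060 as deposited. That call was also lost with arrays centred on their medians (-0.028, adjusted p = 0.101). In these 3 lists 0 members passed, adjusted over the list alone or over all genes. Of the panel, Pdk4 (0.38), Cpt1b (0.20), Slc2a4 (-0.27), Fbxo32 (0.22), Angptl4 (0.75), Ucp3 (0.31), Scd (-0.21) and Adipoq (-0.14) did not pass. limma called 0 genes, with 1170 at an unadjusted p under 0.05, and 1 gene without high-fat/chow replicate 1. As deposited, where the median of all genes shifted by 0.11, it also called 0, and the fibroblast and leukocyte lists, still called, averaged -0.062 and -0.063. The list count fell from 8 to 5 without high-fat/chow replicate 1 or high-fat/high-fat replicate 1. Without high-fat/chow replicate 1 (0.25, adjusted p = 0.290), high-fat/chow replicate 3 (0.24, adjusted p = 0.121), high-fat/chow replicate 4 (0.30, adjusted p = 0.135), high-fat/high-fat replicate 1 (0.24, adjusted p = 0.372) or high-fat/high-fat replicate 2 (0.18, adjusted p = 0.483) the slow-fibre call was lost. Other losses of it came as deposited (0.48, adjusted p = 0.324), with the well column as a block (0.33, adjusted p = 0.0783) and with arrays centred on their medians (0.39, adjusted p = 0.0528). Single animals moved the rise both ways, its mean being 0.59 without high-fat/chow replicate 2 and 0.68 without high-fat/high-fat replicate 4. In the 3 neighbouring pairs of this lineage the high-fat-fed female had the higher slow-fibre score in 1 pair (mean difference 0.20, SD 0.81) and the lower score in the other 2. The immediate early call was lost without high-fat/chow replicate 1 (0.17, adjusted p = 0.132) or high-fat/high-fat replicate 1 (0.18, adjusted p = 0.137), and as deposited (0.33, adjusted p = 0.144).

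Whether the own diet acted differently in the 2 lineages was tested as the interaction. Sntb1 had the largest difference among the genes of smallest p, 1.02 log2 (SE 0.22). It was 10.19 ± 0.16 and 9.45 ± 0.23 in chow/chow and chow/high-fat animals (SD, n = 5 each) and 9.92 ± 0.30 and 10.20 ± 0.36 in high-fat/chow and high-fat/high-fat animals (SD, n = 4 each). Dpp3 (0.66), Slc17a5 (0.62), Pcdhb2 (0.61), Hspbp1 (0.41) and Znfx1 (0.34) differed in the same direction, and Dgkz (-0.66), C8h3orf62 (-0.50), Slc13a1 (-0.41) and Wdr12 (-0.40) in the other, all with adjusted p = 0.546 and none called. Other probe sets of Dgkz gave -0.023 and 0.26. Slow-fibre genes differed as a list, 16 of 16 in the same direction by a mean of 0.62 (camera adjusted p = 0.00162, adjusted p = 0.821 with an estimated correlation), with Ankrd2 (0.82), Myoz2 (0.95), Myh7 (1.12, SE 0.60) and Tnni1 (1.06) leading. Proteasome subunits averaged -0.083, 23 of 32 below 0 (camera adjusted p = 0.0418, adjusted p = 0.821 with an estimated correlation), among them Psmb7 (-0.30), Psma7 (-0.32), Psma2 (-0.39) and Psma5 (-0.34). As deposited the list averaged 0.21 and Psma7 0.0046. The proteasome call held in 7 of 18 runs that left out 1 animal and was lost without chow/chow replicates 1, 2 or 5, chow/high-fat replicates 2, 3, 4 or 5, high-fat/chow replicates 3 or 4 or high-fat/high-fat replicates 3 or 4 (means of -0.084 to -0.063, adjusted p from 0.0632 to 0.204). Further losses came with arrays centred on their medians (-0.000025, adjusted p = 0.589) and without the 2 arrays of lowest median (-0.053, adjusted p = 0.231). In both lists 0 members passed, adjusted over the list alone or over all genes. The interaction did not pass for the oxidation list (0.061, camera adjusted p = 0.296) or the responsive list (0.12, 0.296). Nor did it for the fibroblast (-0.065, 0.345), leukocyte (-0.043, 0.521), fat-cell (-0.042, 0.521) or immediate early (0.20, 0.296) lists. A call in 1 lineage alone is therefore no evidence that the lineages differed. Panel genes other than Myh7 differed by -0.17 (Slc2a4) to 0.26 (Angptl4), apart from Adipoq (-0.34). limma called 0 genes for the interaction, with 863 at an unadjusted p under 0.05, and 1 as deposited, where the median of all genes shifted by 0.24. The slow-fibre call was lost as deposited (0.90, adjusted p = 0.281) and with the well column as a block (0.43, 0.153). It was also lost without chow/high-fat replicate 2 (0.46, adjusted p = 0.0737) or high-fat/high-fat replicate 2 (0.46, adjusted p = 0.0980). The mean was 0.96 without high-fat/high-fat replicate 4. Over both lineages, the high-fat-fed female had the higher slow-fibre score in 1 of 8 neighbouring pairs, a pair of the high-fat lineage. So most pairs of either lineage went the same way, in a comparison made after the values were seen. The number of lists called was 0 without chow/high-fat replicate 2. It was 1 without chow/chow replicates 1, 2 or 5, chow/high-fat replicates 3, 4 or 5, high-fat/chow replicates 3 or 4 or high-fat/high-fat replicate 2. Without chow/high-fat replicate 1 it was 7.

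The next comparison asked whether the muscle of the granddaughters differed with the diet of the grandfather, with animals rather than founders as the units. Averaged over both own diets, 25 genes passed: 20 were higher and 5 lower in the high-fat lineage, with log2 differences of 0.23 to 0.43 in size. Kptn (10704424), which encodes the actin-associated protein kaptin, rose 1.34-fold (log2 change 0.43, SE 0.067, adjusted p = 0.0466). It went from 7.56 ± 0.11 and 7.52 ± 0.038 in the chow/chow and chow/high-fat groups (SD, n = 5 each) to 7.96 ± 0.22 and 7.97 ± 0.18 in the high-fat/chow and high-fat/high-fat groups (SD, n = 4 each). Sdhaf1, an assembly factor of succinate dehydrogenase (0.43), Tafazzin, which remodels cardiolipin (0.30), and Smim20, a small mitochondrial protein (0.38), rose as well. So did Akr1b7 (0.40), Plpp7 (0.38), Pycr3 (0.37), Gosr2 (0.35), the ribosomal protein gene Rpl29 (0.34) and Tbcb (0.33), with SEs of 0.055 to 0.085. The 7 other probe sets of Rpl29 differed by 0.17 to 0.45. The genes that fell were the carboxypeptidase gene Cpo (-0.41, SE 0.070), Slc17a5, which exports sialic acid from lysosomes (-0.37, SE 0.076), Rpl14l2 (-0.33), Phip (-0.29) and the sodium pump subunit Atp1a4 (-0.26). Kptn lay above and Cpo below the mean of the matched chow-lineage group in 8 of 8 animals, Sdhaf1 and Slc17a5 each in 7 of 8. The test in these same animals picked these genes, so such counts are not separate evidence. The difference of Slc17a5 was -0.68 in chow-fed and -0.064 in high-fat-fed animals, but the interaction, which tests whether these differ, did not pass for it. Adjusted p over the 25 genes ran from 0.0466 to 0.0490.

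No list passed in this average: slow-fibre genes averaged -0.31 (camera adjusted p = 0.10), leukocyte markers 0.081 (0.10), chaperones -0.060 (0.104), tendon markers 0.14 (0.141) and fibroblast genes 0.053 (0.208). Imprinted genes averaged -0.032 (0.684), let-7 targets -0.019 (0.555) and chromatin modifiers -0.039 (0.232). In the panel, Scd, which desaturates fatty acids, differed by 0.52 (SE 0.19, adjusted p = 0.199), Myh7 by -0.66 (SE 0.30, adjusted p = 0.303) and Angptl4 by -0.26. Fbxo32 differed by 0.14, Adipoq by -0.092, Slc2a4 by -0.086 and Pdk4 by -0.034, none of which passed. limma gave 1851 genes at an unadjusted p under 0.05, against 632.1 expected by chance. The count was 0 as deposited, where the median of all genes shifted by 0.059 log2, 0 with neighbouring animal numbers as a random block and 0 with the well column as a block. It was also 0 with an offset of 1, with arrays centred on their medians, with the deposited array median as a covariate and without the 2 arrays of lowest median. It was 38 with an offset of 64, 41 with the filter at the 50th percentile, 43 with trended and robust eBayes, 252 with array weights and 108 over all probe sets. The lists called were 7 as deposited, 7 with arrays centred on their medians, 3 without the 2 arrays of lowest median and 1 with the well column as a block, so the absence of a called list depends on the scaling. With 1 animal left out, the gene count was 0 without chow/chow replicates 1, 3 or 5, chow/high-fat replicates 1, 3 or 5, high-fat/chow replicates 2, 3 or 4 or high-fat/high-fat replicates 2 or 4. It was 1 without high-fat/high-fat replicate 3. Without chow/chow replicates 2 or 4 it was 2. It was 6 without chow/high-fat replicate 4. Without chow/high-fat replicate 2 it was 15. It was 38 without high-fat/high-fat replicate 1. Without high-fat/chow replicate 1 it was 305. The list count was 1 without chow/high-fat replicates 1 or 5 or high-fat/chow replicate 2. It was 2 without chow/chow replicate 4 or high-fat/high-fat replicate 1. Without chow/high-fat replicates 2 or 4 it was 3. It was 5 without chow/chow replicate 5 or high-fat/high-fat replicate 2.

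**Figure D3:**
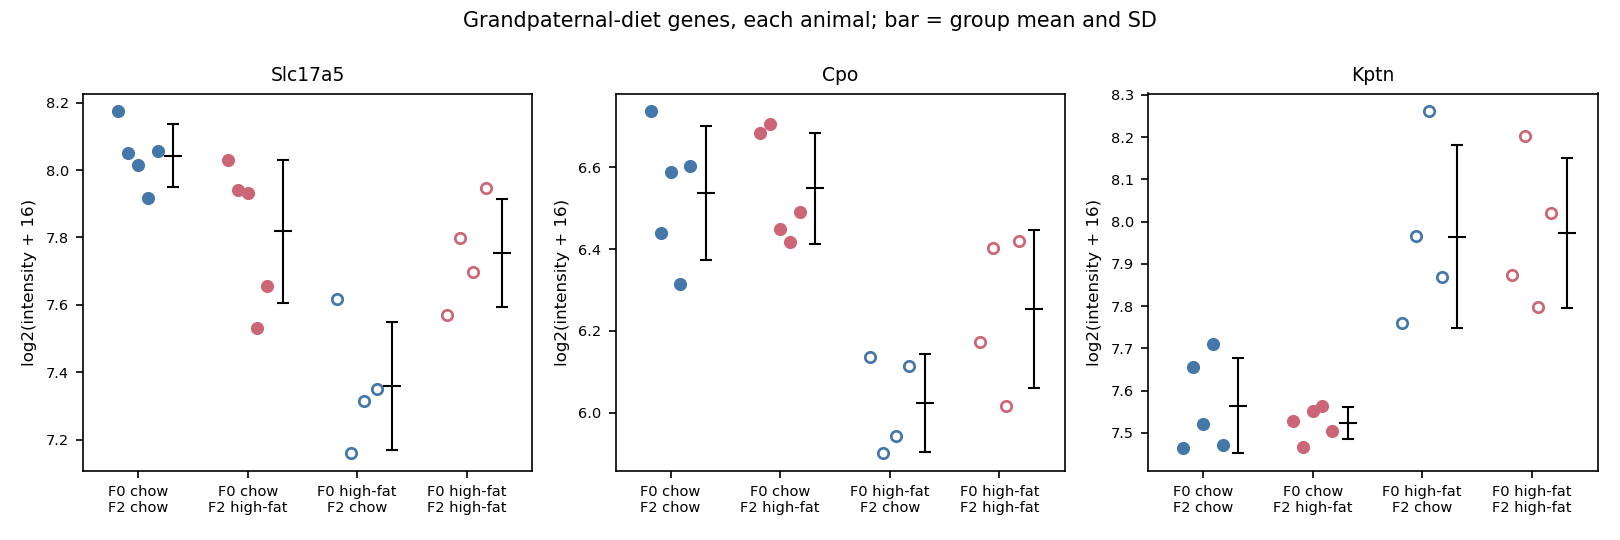
Level of Slc17a5, Cpo and Kptn in each animal, in log2(intensity + 16), by diet of the grandfather (F0) and of the female (F2); bars give group mean and SD. Cpo was 6.54 ± 0.16 and 6.55 ± 0.14 in the chow lineage on chow and high-fat diet and 6.02 ± 0.12 and 6.25 ± 0.19 in the high-fat lineage.

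Among chow-fed granddaughters, 1 gene passed for the diet of the grandfather: Slc17a5 (10918848) fell to 0.623 of its level (log2 change -0.68, SE 0.11, 95% confidence interval -0.91 to -0.46, adjusted p = 0.0484). It went from 8.04 ± 0.093 (SD, n = 5) to 7.36 ± 0.19 (SD, n = 4), lower in 4 of 4 animals. Slow-fibre genes fell as a list, 14 of 16 members lower by a mean of -0.62 (camera adjusted p = 3.00e-05, adjusted p = 0.837 with an estimated correlation). Myh7, the slow myosin heavy chain, differed by -1.22 log2 (SE 0.42, adjusted p = 0.465), the slow troponins Tnnc1 and Tnnt1 by -1.27 and -1.23, and the slow calcium pump Atp2a2 by -1.01. Of the list 0 members passed, adjusted over the list alone or over all genes. The slow-fibre score was 0.28 ± 0.35 in chow/chow (SD, n = 5) and -0.35 ± 0.50 in high-fat/chow animals (SD, n = 4), with a two-sided exact permutation p = 0.0635, 0.524 after adjustment over 30 lists. Within well columns 5 and 7 the grandpaternal difference of that score, both own diets together, was -0.20 and -1.02. In column 7 the high-fat lineage had 2 animals, 1 of each own diet. The high-fat-fed one, high-fat/high-fat replicate 4, stood apart from its group in Myh7, Tnnc1 and Tnnt1. The chow-fed part of column 7 was 1 animal of each lineage, so -1.02 rests on single animals. In column 9 the difference was -0.65, from 1 chow-fed animal of each lineage. Other lists came near the threshold without passing: responsive genes (-0.13), fibroblast genes (0.086, 25 of 33 higher), leukocyte markers (0.10, 19 of 26 higher) and chaperones (-0.088), each at camera adjusted p = 0.0510, and glycolysis (0.055, 0.0532). The next genes by p were Cpo (-0.51, adjusted p = 0.344), Cacna1f (-0.37), Cdc123 (0.26), Ilvbl (-0.41), Sfrp1, a Wnt antagonist (-0.60), Tamm41 (0.32), the growth factor Vegfb (-0.44), Znfx1 (-0.24) and Pcdhb2 (-0.45), all but Cpo at 0.376 and none called. Panel differences other than Myh7 ran from -0.39 (Angptl4) to 0.43 (Scd).

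limma gave 1106 genes at an unadjusted p under 0.05 in this comparison. Slc17a5 missed the threshold as deposited (-0.74, adjusted p = 0.105) and with the well column as a block (-0.69, 0.0516). So it did with offsets of 1 (-0.74, 0.0777) and 64 (-0.55, 0.0540) and with the deposited array median as a covariate (-0.64, 0.0629). Over all probe sets and with the 2 groups alone, 2 and 2 passed. The gene count was 0 without chow/chow replicates 1, 2, 3, 4 or 5, chow/high-fat replicates 2, 3 or 5, high-fat/chow replicates 2, 3 or 4 or high-fat/high-fat replicates 2 or 3. It was 2 without high-fat/chow replicate 1. The log2 difference of Slc17a5 stayed between -0.77 and -0.62 in these runs. The slow-fibre list passed in all 18 runs that left out 1 animal, with means of -0.87 to -0.51. The lists called were 8 as deposited, 8 with arrays centred on their medians, 5 without the 2 arrays of lowest median and 3 with the well column as a block. The list count was 2 without high-fat/chow replicate 4. It was 3 without chow/chow replicate 1 or high-fat/chow replicate 1. Without chow/chow replicates 3 or 5 or high-fat/chow replicate 2 it was 4. It was 5 without chow/chow replicate 4, chow/high-fat replicates 3 or 4 or high-fat/chow replicate 3. Without chow/high-fat replicate 1 it was 7.

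**Figure D4:**
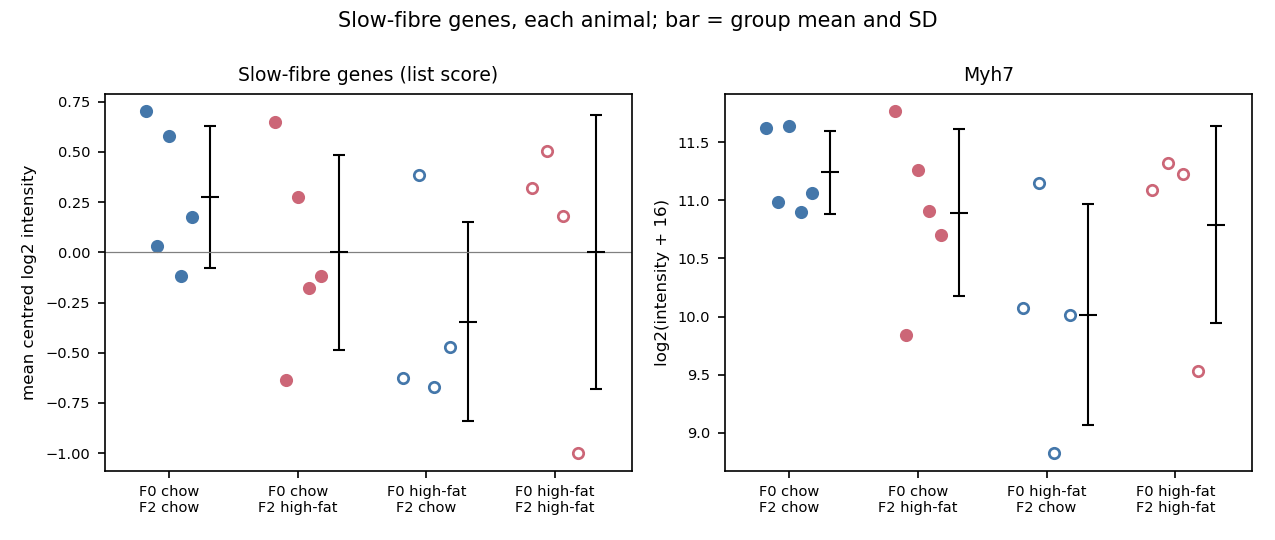
Slow-fibre list score (left, mean centred log2 intensity) and Myh7 level (right, log2(intensity + 16)) of each animal, by diet of the grandfather (F0) and of the female (F2); bars give group mean and SD. Myh7 was 11.24 ± 0.36 in chow/chow, 10.90 ± 0.72 in chow/high-fat, 10.02 ± 0.95 in high-fat/chow and 10.79 ± 0.85 in high-fat/high-fat animals.

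Among high-fat-fed granddaughters, no gene passed for the diet of the grandfather. The sulfate transporter gene Slc13a1 (-0.39, SE 0.062) and LOC297756 (0.62, SE 0.10) came nearest, at adjusted p = 0.0537 (n = 5 and 4). They were followed by Ubxn6 (0.39) and Phf8l (-0.42) at 0.0981. Next were Med11 (0.57), Gosr2 (0.49), Dpp3 (0.52), Rpl10al3 (0.53), Sdhaf1 (0.58) and Kptn (0.45) at 0.0990. Scd was higher by 0.62 (SE 0.26, adjusted p = 0.317) and Fbxo32 by 0.22 (SE 0.10, adjusted p = 0.375). Myh7 differed by -0.11 (SE 0.42) and the slow-fibre list by 0.0015, whose difference from the chow-fed granddaughters is the interaction. No list passed. Tendon markers averaged 0.22 (camera adjusted p = 0.189), chromatin modifiers -0.063 (0.238), endothelial markers 0.088 and the oxidation list -0.0014 (median 0.025). limma called 0 genes, with 1682 at an unadjusted p under 0.05. As deposited, where the median of all genes shifted by 0.18 log2, it called 1689 genes, 1686 of them higher. So this comparison depends on how the arrays are brought to a common level. An offset of 1 gave 1 gene and all probe sets 13. The lists called were 4 as deposited, 4 with arrays centred on their medians and 2 without the 2 arrays of lowest median. The gene count was 1 without high-fat/chow replicate 3. It was 3 without chow/chow replicate 2. Without high-fat/chow replicate 1 it was 55. It was 56 without high-fat/high-fat replicate 1. The list count was 1 without high-fat/high-fat replicate 4. It was 2 without chow/high-fat replicate 1.

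Each diet could be compared across the other with no animal in common. Over the 12642 genes, which are not independent replicates, the changes with the own diet in the chow lineage and those in the high-fat lineage had Pearson's r = 0.0190 (Spearman's rho = -0.0312, two-sided permutation p = 0.812), with 95% of 100 regroupings between -0.206 and 0.240. The grandpaternal differences in chow-fed and in high-fat-fed granddaughters had r = 0.221 (rho = 0.212, permutation p = 0.109), with 95% of regroupings between -0.245 and 0.256. Neither passed in this family of 2 relations. Decr1 gave like values in both lineages (0.58 and 0.59), but it was picked by its average over them. Like values therefore follow in part from that choice. The oxidation list, whose members were set beforehand, gave 0.21 and 0.27. Without chow/high-fat replicate 1, r was -0.102 for the own diet and 0.112 for the grandpaternal diet.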

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

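The tests on the well column, genomic gene length, the quantile step, slow fibres and fat cells were chosen only after the results were seen. For each list called in some comparison, the array medians and each gene the text names, the most distant animal of each group was set against the others of its group by Dixon's ratio at 95%. Of 588 group tests 31 passed, and chance alone gives about 29.4. Apart from the rest of their group stood chow/high-fat replicate 1 in the proteasome score (-0.121 against 0.0117 to 0.0537), Dcn (11.94 against 11.55 to 11.65), Dpp3 (7.60 against 7.16 to 7.28), Nr4a3 (7.21 against 5.74 to 6.10) and Pak1 (7.51 against 7.74 to 7.82), high-fat/chow replicate 4 in Angptl4 (6.45 against 6.93 to 7.02) and chow/high-fat replicate 4 in Ankrd2 (8.08 against 8.89 to 9.04), Cdc123 (9.19 against 9.05 to 9.09) and Rpl29 (10.95 against 11.10 to 11.16). So did chow/chow replicate 2 in Cat (11.36 against 11.54 to 11.61), chow/chow replicate 4 in Cd68 (6.29 against 5.89 to 5.95), Tap1 (6.30 against 5.79 to 5.91), Tlr3 (9.67 against 9.41 to 9.48) and Tmem106a (5.93 against 5.68 to 5.73) and high-fat/chow replicate 2 in Cers4 (7.18 against 6.87 to 6.92) and Crat (11.95 against 12.00 to 12.01). Further values came from high-fat/chow replicate 3 in Chad (9.39 against 10.19 to 10.20), chow/chow replicate 5 in Col14a1 (8.32 against 7.95 to 8.04) and chow/high-fat replicate 2 in Crls1 (8.36 against 8.55 to 8.63). The list goes on with high-fat/high-fat replicate 3 in Ifit2 (7.39 against 7.09 to 7.11), high-fat/chow replicate 1 in Lipe (8.38 against 8.11 to 8.13) and Scx (6.91 against 7.48 to 7.60) and chow/chow replicate 3 in Mrc1 (7.06 against 7.57 to 7.65). Also apart were high-fat/high-fat replicate 4 in Myh7 (9.53 against 11.09 to 11.32), Tnnc1 (7.21 against 9.44 to 9.77), Tnnt1 (8.18 against 10.24 to 10.40) and Wdr12 (9.60 against 9.71 to 9.72), chow/high-fat replicate 5 in Retn (4.99 against 5.56 to 5.79) and high-fat/high-fat replicate 2 in Scd (7.66 against 8.38 to 8.40). The remaining values were high-fat/high-fat replicate 1 in Scx (7.69 against 7.29 to 7.33) and chow/high-fat replicate 3 in Ucp3 (10.08 against 11.22 to 11.43). Values are log2, or mean centred log2 for a score. The slow-fibre values of high-fat/high-fat replicate 4 lie together, in Myh7, Tnnc1 and Tnnt1, and no animal was left out for them.

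The interaction test passed for the slow-fibre list (0.623) and the proteasome list (-0.0828), each with an adjusted p of 0.821 once the correlation is estimated. When all 15687 probe sets above the filter were tested, 3045 of them outside the tested genes, the grandpaternal diet gave 1 called probe set outside those genes at own chow, 9 at own high-fat diet and 47 in the average. They were not analysed here.

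Other splits of the same animals, the real one counted, show how often a grouping made without regard to the diet called as many. For genes this was 2 of 100 splits (2 real, 5 highest other) in the own-diet average and 1 of 100 splits (25 real, 1 highest other) in the grandpaternal average. Both shares lie under 0.05, but neither was adjusted over the other tests of this kind. In the own-diet average another split called more genes than the real one. The grandpaternal splits part neighbouring animals, and splits that keep them together reached 17 genes. So chance is not called excluded in either average. It is not excluded for the gene of the grandpaternal diet at own chow, 5 of 100 splits (1 real, 1 highest other). Nor is it excluded for the lists called with the own diet, 16 of 100 splits (9 real, 13 highest other) in the average, 26 of 100 splits (8 real, 14 highest other) in the chow lineage and 8 of 35 splits (8 real, 13 highest other) in the high-fat lineage, with the grandpaternal diet at own chow, 86 of 100 splits (1 real, 12 highest other), or in the interaction, 88 of 100 splits (2 real, 15 highest other). Where the real count is 0, every split gives as many and nothing is tested: genes with the own diet in the chow lineage, 100 of 100 splits (0 real, 1 highest other), and the high-fat lineage, 35 of 35 splits (0 real, 14 highest other), with the grandpaternal diet at own high-fat diet, 100 of 100 splits (0 real, 14 highest other), and in the interaction, 100 of 100 splits (0 real, 2 highest other). The same holds for lists with the grandpaternal diet in the average, 100 of 100 splits (0 real, 15 highest other), and at own high-fat diet, 100 of 100 splits (0 real, 13 highest other). The highest count of another split was 14 genes where the real one called 0, with the own diet in the high-fat lineage and with the grandpaternal diet at own high-fat diet. Whether a structure of the samples lies behind such splits was not tested. The list counts of the splits cannot show it, since the preset correlation of 0.01 lies below the estimates of many lists, 0.469 for oxidation for example, and that alone can raise list calls in any split.

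Animals of 1 lineage whose numbers lie 3 or fewer apart resembled each other: after the group means were removed, the 8 pairs had a mean correlation of 0.186 over genes (0.414, 0.158, 0.351, 0.126, 0.170, -0.0366, 0.199 and 0.109). Of 2880 redrawn pairings, with a median of -0.00755, none of the others reached this, a one-sided exact p of 0.000347, the smallest they can give (0.00833 in the chow and 0.0417 in the high-fat lineage). Pairs that share a well column had 0.414, 0.351, 0.126 and 0.199, and the other pairs 0.158, 0.170, -0.0366 and 0.109. With the column in the fit the mean was 0.146 and the exact p 0.00764. That fit gives a column the same effect on all its arrays. If columns pool plates, it cannot remove an effect within a plate, so a shared column is not excluded as a source. Clock and immediate early genes, 44 in all, had a mean pair correlation of 0.337, at percentile 94.8 of 10000 random lists (median 0.174), so a shared hour of dissection or handling cannot be told apart from kinship, the percentile falling just short of 95. A shared litter may be the source, which the labels do not record.

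Splits that keep neighbouring animals together, with the 2 lone animals treated as a pair, gave as many genes as the grandpaternal average called in 1 of 100 (25 real, 17 highest other), but as high a correlation between own diets in 33 of 100 (0.221 real, 0.474 highest other), tests written when the real count, that correlation and the pair correlations were known. With neighbours as a random block 0 genes passed, the folds of the 25 genes being 0.987 to 1.01 of those without it: the calls ended because the median SE went from 0.0574 to 0.0599 and the adjusted p to 0.0803 or more, not because the difference shrank. Families may account for the correlation, and each lineage may descend from few founders, which was not tested. A difference between plates could not be tested, since the labels do not name plates. A trend with gene length is argued against, as the folds after its removal were 0.984 of those before (median ratio) with 28 genes called. The quantile step did not make the folds, which with median centring had a median ratio of 1.05, although 0 genes then passed because the median SE went from 0.0574 to 0.0652 and the lowest adjusted p to 0.0713.

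Genes of fatty acid oxidation rose with the own high-fat diet by a median of 0.229 log2. More fat cells in the muscle would bring their abundant transcripts. Of the markers chosen for this, Lep and Adrb3 were not among the tested genes. The 6 that were had a median of 0.0353, and the standard error of their mean across genes was 0.0308. They were Adipoq at 0.030, Plin1 at 0.062, Cidec at -0.073, Retn at 0.041, Cfd at -0.12 and Pck1 at 0.045. Their SEs over animals ran from 0.058 (Pck1) to 0.19 (Adipoq). The whole fat-cell list of 14, with Aqp7, Lipe, Cidea and Plin4, several of which fibres also express and none of which were among the 6, had a median of 0.043 and a mean of 0.17. But 5 of the 6 had a mean level of 5.46 to 6.24 log2, within 1 log2 of the filter at 5.28, and Adipoq an SE of 0.19, so fat cells cannot be told apart from a response of the fibres to dietary fat, which may be a hypothesis for a larger set of animals. With the slow-fibre score as a covariate the rise was 0.232 over both lineages, a ratio of 0.999. That decides nothing because the score, with each animal weighted alike, differed by 0.00103 (-0.518 to 0.520). As the mean of the 2 lineages the score differed by 0.036. In the chow lineage the rise was 0.248 (0.115 to 0.382), 1.21 of that without the covariate. The score was lower with the high-fat diet there (-0.276), so a ratio above 1 follows where oxidation rises with the score, and it decides nothing. The lower score gives no sign of a larger share of slow fibres in that lineage, though its fall was lost in several settings. In the high-fat lineage the rise was 0.193 (0.0447 to 0.341), a ratio of 0.726, so slow fibres cannot be told apart from a response as the source of part of it.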

How the results depend on the processing

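Median centring, the array median as a covariate, the exact permutation and leaving out the 2 dimmest arrays were chosen after seeing the data. The counts to compare are 0, 0, 1, 0, 0, 2 and 25 genes and 8, 8, 1, 0, 2, 9 and 0 lists for the own diet in the chow and high-fat lineages, the grandpaternal diet at own chow and own high-fat diet, the interaction, the own-diet average and the grandpaternal average. As deposited the genes called were 1 (own diet in the chow lineage), 0 (grandpaternal diet at own chow), 1689 (grandpaternal diet at own high-fat diet), 1 (interaction), 4 (own-diet average) and 0 (grandpaternal average), 1686 of the 1689 being higher, and the lists 8 (grandpaternal diet at own chow), 4 (grandpaternal diet at own high-fat diet), 0 (interaction) and 7 (grandpaternal average). As deposited these turned sign: Psma7 in the interaction (0.0046), the fast-fibre list (0.0091) and the proteasome list (0.060) with the own diet in the high-fat lineage, and the proteasome list in the interaction (0.21). An offset of 1 gave 0 (grandpaternal diet at own chow), 1 (grandpaternal diet at own high-fat diet), 0 (own-diet average) and 0 (grandpaternal average), and 64 gave 0 (grandpaternal diet at own chow), 6 (own-diet average) and 38 (grandpaternal average). The filter at the 50th percentile gave 41 (grandpaternal average), all probe sets 2 (grandpaternal diet at own chow), 13 (grandpaternal diet at own high-fat diet) and 108 (grandpaternal average), trended and robust eBayes 5 (own-diet average) and 43 (grandpaternal average), array weights 6 (own-diet average) and 252 (grandpaternal average) and the 2 groups alone 2 (grandpaternal diet at own chow). The well column as a block gave 0 (grandpaternal diet at own chow), 15 (own-diet average) and 0 (grandpaternal average) genes and 3 (grandpaternal diet at own chow), 1 (interaction) and 1 (grandpaternal average) lists. Neighbouring animals as a random block gave 14 (own-diet average) and 0 (grandpaternal average). Median centring gave 5 (own-diet average) and 0 (grandpaternal average) genes and 8 (grandpaternal diet at own chow), 4 (grandpaternal diet at own high-fat diet) and 7 (grandpaternal average) lists. The deposited array median as a covariate gave 0 (grandpaternal diet at own chow), 0 (own-diet average) and 0 (grandpaternal average). Without the 2 arrays of lowest median, chow/high-fat replicates 4 and 5, there were 0 (own-diet average) and 0 (grandpaternal average) genes and 5 (grandpaternal diet at own chow), 2 (grandpaternal diet at own high-fat diet), 1 (interaction) and 3 (grandpaternal average) lists. With an estimated correlation the lists called were 0 (own diet in the chow lineage), 0 (own diet in the high-fat lineage), 0 (grandpaternal diet at own chow), 0 (interaction) and 1 (own-diet average), with fry 0 (own diet in the chow lineage), 1 (own diet in the high-fat lineage), 0 (grandpaternal diet at own chow), 0 (interaction) and 2 (own-diet average) and with exact permutation of animals 0 (own diet in the chow lineage), 0 (own diet in the high-fat lineage), 0 (grandpaternal diet at own chow) and 2 (own-diet average).

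Leaving out each array in turn gave 0 to 0 genes for the own diet in the chow lineage, 0 to 1 genes for the own diet in the high-fat lineage, 0 to 2 genes for the grandpaternal diet at own chow, 0 to 56 genes for the grandpaternal diet at own high-fat diet, 0 to 0 genes for the interaction, 0 to 14 genes for the own-diet average and 0 to 305 for the grandpaternal average. The lists called ran 7 to 9 for the own diet in the chow lineage, 5 to 11 for the own diet in the high-fat lineage, 1 to 7 for the grandpaternal diet at own chow, 0 to 2 for the grandpaternal diet at own high-fat diet, 0 to 7 for the interaction, 7 to 11 for the own-diet average and 0 to 5 for the grandpaternal average. The correlation ran from -0.102 to 0.126 for the own diet and from 0.112 to 0.313 for the grandpaternal diet. Of the other values for named genes and lists, leaving out an array kept 4258 with the same sign and on the same side of the threshold, made 319 weaker and 33 stronger and moved 70. The other settings kept 2806 in this sense, made 208 weaker and 47 stronger and moved 43. Here weaker means that a call was lost, stronger that a call was gained, and moved that the sign of a value not called turned. The titles carry no shared replicate numbers to fit as a block; neighbouring animal numbers, which the labels do not explain, were used as a random block and for pairs instead. The cause of these differences was not tested.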

Other observations

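Each of the 8 neighbouring pairs holds 1 chow-fed and 1 high-fat-fed female of 1 lineage, so the own diet can be read within pairs, a comparison made after the values were seen. The genes and lists read here were picked by the own-diet comparison in these same animals. Their counts were therefore largely set by that choice and are not separate evidence. The high-fat-fed animal was higher for Decr1 in 8 of 8 pairs (mean 0.55, SD 0.34), for Nudt7 in 8 of 8 pairs (mean 0.59, SD 0.33), for the lipid-droplet gene Plin5 in 8 of 8 pairs (mean 0.73, SD 0.44) and for the glycerol channel gene Aqp7 in 8 of 8 pairs (mean 1.25, SD 0.78). It was higher for the oxidation list in 8 of 8 pairs (mean 0.22, SD 0.19) and for the fatty-acid-responsive list in 8 of 8 pairs (mean 0.32, SD 0.18). Fat-cell markers were higher in 7 of 8 pairs (mean 0.17, SD 0.17), fibroblast markers in 1 of 8 pairs (mean -0.15, SD 0.15) and leukocyte markers in 1 of 8 pairs (mean -0.16, SD 0.13). Of the other lists called in the own-diet average, tendon markers were higher in 3 of 8 pairs (mean -0.23, SD 0.33), interferon-stimulated genes in 2 of 8 pairs (mean -0.090, SD 0.093), proteasome subunits in 2 of 8 pairs (mean -0.033, SD 0.064) and immediate early genes in 6 of 8 pairs (mean 0.085, SD 0.24). Downstream of these enzymes, genes of the tricarboxylic acid cycle differed by -0.0027 and nuclear respiratory chain genes by -0.0060 in the own-diet average. Neither passed, which does not show that they did not differ.

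Among the 25 genes of the grandpaternal average, Tamm41 (0.25), Pgs1 (0.25, adjusted p = 0.0490) and Tafazzin (0.30) act in the making and remodelling of cardiolipin, the lipid of the inner mitochondrial membrane, while Crls1, the synthase of the same route, differed by -0.019 (adjusted p = 0.903). This link was noticed after the values were seen, and Pgs1 and Crls1 lie outside the naming rule. None of the 30 lists covers the route and its share of the called genes was not tested, so the 3 genes are no evidence of an effect on the route. With neighbours as a random block Tafazzin differed by 0.30 with an adjusted p of 0.0807 and 0 genes passed. 

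The slow-fibre list was lower in high-fat/chow than in chow/chow animals and kept its call in 18 of 18 runs without 1 animal. Its members did not pass singly, over all genes or over the list alone, Myh7 (-1.22 log2) having an adjusted p of 0.465. A smaller share of slow fibres may lie behind it, or where the muscle was sampled, or families of animals, and none of these was tested. An estimated correlation between its genes leaves an adjusted p of 0.837, with 86 of 100 splits calling as many lists. Fibre typing of sections taken at a matched site of the muscle in both lineages would be needed to tell a change of fibres from a change of dissection.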
